A study of Homo sapiens with 76 samples.

How the data were processed

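The series holds exon array profiles of 76 samples, of which 73 are cell lines and 3 normal tissue RNA. Per the labels, total RNA with the small RNA fraction was extracted with the Qiagen miRNeasy kit, RNA integrity numbers were above 8.5, and 100 ng of total RNA was labelled with the Affymetrix WT terminal labelling kit and hybridised to Human Exon 1.0 ST arrays. The authors' values are RMA expression on the log2 scale, per the submitters' processing notes and the range of the deposited values (2.05 to 14.47); the version of RMA and the annotation it used are not given in the sources used here. RMA corrects background, normalizes arrays to one distribution and summarises probes, so a change of total RNA content per cell leaves no trace in the values. The authors also deposited a table of median log10 IC50 per compound and line. Its concentration unit is not stated. Its lowest value of -2.82 equals log10 of 10 divided by 3 to the power 8, and its most common value, 1, holds 58.9% of all entries, so an entry of 1 was read as no IC50 reached within the range, although 39 entries lie above it; only differences of log10 IC50 are free of the unit. Compounds are given there by NSC number; names were assigned from general knowledge of NSC numbers, before the data were examined except for thiotepa and triethylenemelamine, and compounds without such a name are called known by number only.

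Probe sets were named through the platform annotation: 254891 of 284258 had 1 gene symbol, and 29367 had none there and were left out, as were 292 probe sets of sex-linked transcripts. The value of a gene was the median over its probe sets (15778 genes, median 13 probe sets a gene, 132 genes with 1). Probe sets of different exons of a gene need not agree, which the mean in place of the median tested. Groups were taken from the labels. Columns of the expression table, and the lines of the IC50 table, were matched to the samples. NCI-H660 and NCI-H720 are labelled as SCLC and were kept; fits without them were made because repositories list them under other diagnoses.

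Group comparisons used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes) with a mean per group over all 76 arrays (69 residual degrees of freedom), so that groups of 1 to 3 arrays were assumed to vary like the others. Adjusted p-values are Benjamini-Hochberg over all genes, with a threshold of 0.05, and tests are two-sided. Gene lists, 22 with 4 or more measured members, were tested with camera (preset inter-gene correlation 0.01, adjusted over 66 tests), with an estimated correlation and with fry as alternatives. Exon usage was tested with diffSplice (Simes p per gene) on 120481 probe sets, those of genes with 3 or more probe sets and a mean above the median of all gene values in both groups. A fit of each probe set relative to its gene with its own spread was added after seeing the data, because diffSplice made many calls on unchanged simulated genes. Drug regressions were limma fits of expression on log10 IC50 over SCLC lines, for compounds with 20 or more lines and at most 50% of lines at 1 value (222 compounds), with 100 permutations. Talazoparib, alisertib and navitoclax, also planned, were not analysed here. Overall drug sensitivity of a line was its mean standardised log10 IC50 over these compounds. Correlations used 100000 permutations in scipy 1.17.1, two-sided, and lines were split into clusters where a Gaussian mixture of 2 components (scikit-learn 1.9.0) gained over 10 BIC units with an Ashman D over 2 and 6 or more lines in each. Of 85 listed pairs of a gene and a drug, 29 could be tested, and of 19 pairs of related compounds 9; intervals are bootstrap intervals of 10000 draws. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and matplotlib 3.10.9 drew the plots.

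Genes named in the text follow a rule: the 10 largest and 10 smallest log2 differences past the threshold in each group comparison; of each list up to 4 members with the largest absolute difference, plus fixed subtype regulators and the genes of the gene and drug pairs; for derivatives the 5 largest differences each way and up to 10 genes over 2 the same way in all 3; for drugs the 5 largest t each way past the threshold; for exon usage the 5 smallest p and a fixed set. Groups, tests, lists, this rule and the alternatives of the closing section were fixed before the data were examined, except where the text says otherwise. Some items are not reported here. Scripts were tested on simulated data: group fits recovered 50.7%, 32.8% and 22.4% of genes changed by 1 on the log2 scale for NSCLC, normal lung and fibroblast groups and 94.0%, 85.1% and 85.1% of those changed by 2, with 9, 8 and 4 unchanged genes called among 15778; the topotecan regression recovered 64% of genes with a slope of 0.5 gene SD per SD of IC50, with 4 unchanged genes called; correlations recovered 20 of 20 related pairs, with 1 of 20 unrelated called.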

Results

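Expression was measured on Affymetrix Human Exon 1.0 ST arrays, which carry probes along the exons of each gene, with 1 array per sample and 76 arrays in all. The panel held 64 small cell lung cancer (SCLC) lines, a neuroendocrine lung tumour. It also held 3 non-small cell lung cancer (NSCLC) lines (A549/ATCC, NCI-H1650 and NCI-H2066) and 3 lines made drug resistant from the SCLC line NCI-H69. The rest were 1 mesothelioma line (NCI-H28), the fibroblast lines MRC-9 and WI-38, 2 arrays of normal lung RNA and 1 of normal adrenal RNA. A second table gave the log10 IC50, an inhibitory concentration, of compounds over 70 of the lines, 63 of them SCLC lines. Of these compounds, 222 varied enough over the SCLC lines to be used. The median probe set value per array lay between 7.39 and 7.45 on the log2 scale. Across genes, which are not independent replicates, pairs of SCLC lines correlated at a median r of 0.86 (0.75 to 0.94), the fibroblast lines at 0.94 and the normal lung arrays at 0.96. Of the NSCLC lines only NCI-H1650 correlated best with another of them (NCI-H2066, r = 0.86). NCI-H2066 correlated best with the SCLC line DMS273 (0.87) and A549/ATCC with the mesothelioma line (0.86). The lines are separate cultures, while nothing in the labels says whether the normal lung arrays came from separate donors, and p-values measure only spread between these samples. In the group comparisons this is mostly spread among the 64 SCLC lines, since all 76 arrays share the same model. The number of arrays limits the precision of each group mean.

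The first comparison asked what sets SCLC lines apart from other lung cancer lines. BEX1, an adaptor protein of neural cells, was higher by 4.70 on the log2 scale (SE 0.76, limma adjusted p = 4.87e-06) and lay above all NSCLC lines in 62 of 64 SCLC lines. NCAM1, the neural cell adhesion molecule, was higher by 4.24 (SE 0.67, adjusted p = 2.86e-06) and also lay above in 62. The calmodulin-binding PCP4 (5.11), the synaptotagmins SYT14 (4.34) and SYT4 (4.17), HEPACAM2 (4.30), the transcription factor ST18 (4.08), the neuronal TAGLN3 (3.95), the neuronal kinesin KIF5C (3.83) and the secretory granule protein SCG3 (3.81) completed the 10 genes with the largest positive difference. In the other direction TGM2, a transglutaminase, had a log2 difference of -4.62 (SE 0.32, adjusted p = 1.28e-18), and TGFBR2, a receptor of TGF-beta, stood at -4.70 (SE 0.52, adjusted p = 2.19e-10). Both lay below every NSCLC line in 64 of 64 SCLC lines. The other genes with the lowest differences were the annexin ANXA1 (-5.99), the proteoglycan SRGN (-5.14), the caveolae protein CAV1 (-5.10), the interferon-induced IFITM1 (-4.98) and IFITM2 (-4.63), the membrane repair protein MYOF (-4.97), the oncostatin M receptor OSMR (-4.88) and the lysosomal protease CTSL (-4.62).

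Among the gene lists fixed in advance, 14 of the 27 measured neuroendocrine genes were higher in SCLC lines and none was lower, and 19 were higher adjusted over the list alone. NCAM1, SYT4, SCG3 and the neuronal RNA-binding ELAVL3 (3.47) led this list (camera adjusted p = 7.94e-14, and adjusted p = 0.0431 with an estimated correlation). Of 40 cell cycle genes, 32 were higher (36 adjusted over the list alone), with adjusted p = 1.23e-29, and adjusted p = 0.00726 with an estimated correlation. The cyclin CCNE2 (3.32), the checkpoint kinases BUB1B (2.19) and TTK (2.12) and the kinetochore protein CENPF (2.09) led it. Of 17 targets and members of the YAP and TEAD growth control pathway, 12 were lower (13 adjusted over the list alone), with adjusted p = 4.42e-12, and adjusted p = 0.038 with an estimated correlation. These estimated values are adjusted over all 66 list tests. Adjusted within this comparison, an alternative chosen after seeing the data, the cell cycle list keeps its call (adjusted p = 0.0169 with an estimated correlation), and the neuroendocrine and YAP and TEAD lists do not (adjusted p = 0.0508 for both). Among the lower YAP and TEAD genes were CRIM1 (-4.46), the ecto-nucleotidase NT5E (-4.23) and the co-activators WWTR1 (-3.82) and YAP1 (-3.69).

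Another 5 lists passed camera with the preset correlation and not with an estimated one. With fry the mesenchymal list lost its call (fry adjusted p = 0.0806) and the others kept theirs. Of 21 interferon response genes, 13 were lower (19 adjusted over the list alone), with IFITM3 at -3.69, IFIT3 at -3.22 and IFI44L at -2.96 (adjusted p = 4.60e-13, and adjusted p = 0.0508 with an estimated correlation). Of 23 DNA damage response genes, 11 were higher and 2 lower (12 and 2 adjusted over the list alone), with adjusted p = 0.00011, and adjusted p = 0.161 with an estimated correlation. The exonuclease EXO1 stood at 2.04, topoisomerase TOP2A at 1.65, PARP1 at 1.55 and the kinase WEE1 at 1.38. Of 15 class I antigen presentation genes, 4 were lower (8 adjusted over the list alone), with adjusted p = 0.000169, and adjusted p = 0.38 with an estimated correlation. HLA-E stood at -2.16 and the peptidase ERAP1 at -1.68, while HLA-B at -2.16 (SE 0.87, adjusted p = 0.0936) did not pass. Of 15 drug transporters, 5 were lower (6 adjusted over the list alone), with the efflux pumps ABCC3 at -3.25, ABCC2 at -2.47 and ABCG2 at -2.24 (adjusted p = 0.00224, and adjusted p = 0.0778 with an estimated correlation). Of 23 mesenchymal genes, 5 were lower (6 adjusted over the list alone), among them CAV1, the protease inhibitor TIMP1 (-4.37) and the matrix protein TGFBI (-3.74), with adjusted p = 0.0147, and adjusted p = 0.622 with an estimated correlation. The remaining 14 lists (among them tuft cell, epithelial, alveolar and airway, leukocyte, endothelial, erythroid, adrenal cortex, adrenal medulla, MYC family, Notch pathway, BCL2 family, glutathione and NRF2 targets, surface targets) did not pass, with adjusted p from 0.117 to 0.974.

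Single members of those lists still differed. The cell cycle inhibitor CDKN2A was higher by 3.12 (SE 0.36, adjusted p = 1.48e-09), while cyclin CCND1 stood at -1.87 (SE 0.37, adjusted p = 0.000172), and RB1, the retinoblastoma protein that SCLC commonly loses, at -0.83 (SE 0.76, adjusted p = 0.554). The inhibitory Notch ligand DLL3 was higher by 1.64 and DLL1 by 2.01, and REST, a repressor of neuronal genes, stood at -1.93 (SE 0.54, adjusted p = 0.00928). The survival factor BCL2 was higher by 1.90, the receptor kinase KIT by 3.29 and the glutathione transferase GSTA4 by 2.69, whereas the hyaluronan receptor CD44 (-4.44) and the receptor kinase EGFR (-2.49) were lower. MYC differed by -1.87 (SE 1.16, adjusted p = 0.329), MYCL by 0.57 and MYCN by 0.42, none past the threshold. Markers of blood cells did not all move one way, with CD68 at -2.75 and CORO1A at 1.42.

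Over all genes, limma called 866 of 15778 higher and 1181 lower in SCLC lines at an adjusted p under 0.05, and 3922 had an unadjusted p under 0.05. With NCI-H1650 left out the counts were 476 and 681, with A549/ATCC left out 435 and 760, and with NCI-H2066 left out 513 and 840. With 3 NSCLC arrays, a simulated log2 difference of 1 was recovered for 50.7% of genes and one of 2 for 94.0%.

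**Figure D1:**
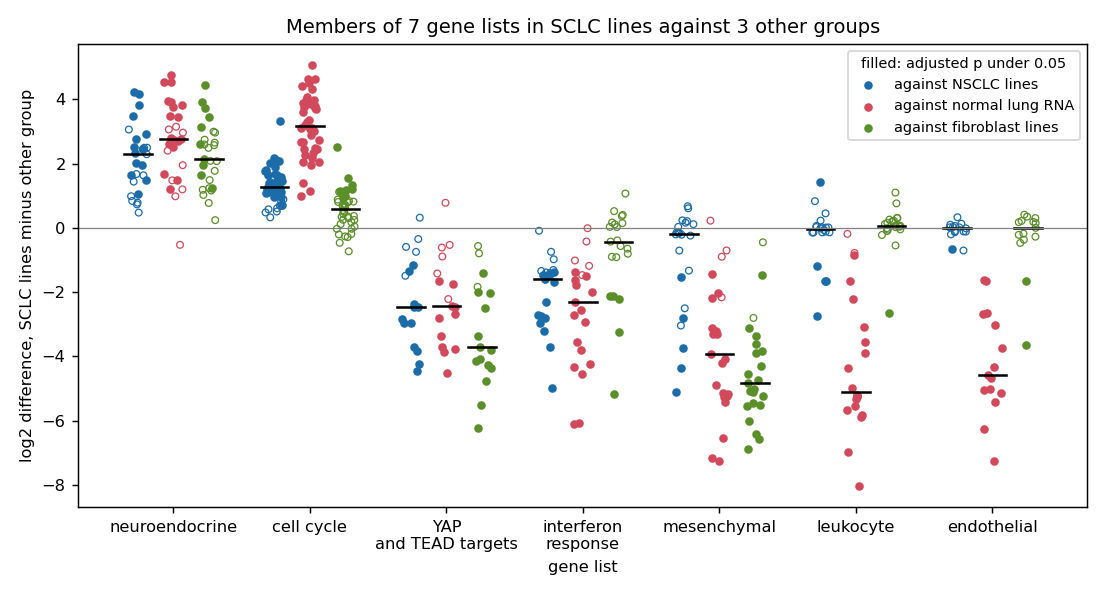
Log2 difference (SCLC lines minus the other group, y axis) of each measured member of 7 gene lists (x axis), with 1 point per gene, filled where the adjusted p was under 0.05, and a bar at the list median. Colours mark the comparison with NSCLC lines (n = 3), normal lung RNA (n = 2) and fibroblast lines (n = 2); the leukocyte and endothelial lists lie far below 0 against normal lung RNA (medians -5.10 and -4.57) and near 0 against the cell lines.

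Against normal lung RNA the same model asked how the cultured tumour lines differ from the tissue of origin, which also holds blood, vessel, stromal and airway cells. LYZ, the lysozyme of macrophages and airway glands, had the lowest difference, -8.04 (SE 0.29, adjusted p = 2.86e-37), and INA, a neurofilament protein, the highest, 5.34 (SE 0.64, adjusted p = 1.43e-10); each separated all 64 SCLC lines from both lung arrays. Other genes far lower in the lines were the protease inhibitor A2M (-7.55), the endothelial PECAM1 (-7.25), the matrix proteoglycans LUM (-7.24) and DCN (-7.17), EVI2B (-7.12), complement factor C7 (-7.09), TMEM100 (-7.08) and the class II antigen presentation genes HLA-DRA (-6.97) and HLA-DPA1 (-6.89). The other genes with the highest differences were topoisomerase TOP2A at 5.07, the kinetochore protein NUF2 at 4.87, the spindle protein DLGAP5 at 4.66 and the cyclin CCNB2 at 4.65, with BEX1 at 4.92, SYT14 at 4.83, MLLT11 at 4.78, SYT1 at 4.76 and TAGLN3 at 4.69.

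All 40 cell cycle genes were higher (40 adjusted over the list alone), with BUB1B at 4.62 and the kinase CDK1 at 4.50 (adjusted p = 3.32e-31, and adjusted p = 0.00614 with an estimated correlation). Markers of the other cells of lung tissue were lower together. These were 18 of 20 leukocyte genes (CD74 -5.87, FCGR3A -5.83), 15 of 15 endothelial genes (LYVE1 -6.26, VWF -5.43, TEK -5.13), 5 of 5 erythroid genes (HBB -6.66, HBD -4.68), 16 of 18 alveolar and airway genes (surfactant protein SFTPB -6.36, SCGB3A2 -6.00, BPIFB1 -5.72) and 19 of 23 mesenchymal genes (CAV1 -6.55, POSTN -5.42). Adjusted over the list alone these counts were 18, 15, 5, 18 and 20, and each list kept its call with an estimated correlation, at adjusted p = 5.52e-07, 9.33e-07, 0.00921, 8.85e-06 and 0.0413. The neuroendocrine list had 18 of 27 members higher (21 adjusted over the list alone), with SYT4 at 4.55 and the neuronal hydrolase UCHL1 at 4.53 (adjusted p = 3.78e-05, and adjusted p = 0.372 with an estimated correlation). Another 4 calls were lost with an estimated correlation. Of YAP and TEAD targets 11 of 17 were lower (12 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation), and of class I antigen presentation genes 10 of 15 (13 adjusted over the list alone, adjusted p = 0.372 with an estimated correlation). Of interferon response genes 16 of 21 were lower (17 adjusted over the list alone, adjusted p = 0.161 with an estimated correlation), and of DNA damage response genes 14 of 23 were higher (15 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation). Among them YAP1 stood at -3.37, HLA-E at -4.45, IFITM3 at -6.11 and the checkpoint kinase CHEK1 at 3.87. DLL3 was higher by 2.60 and CDKN2A by 2.62, while SLFN11, a restriction factor of stalled replication, differed by -2.48 (SE 1.34, adjusted p = 0.142). Over all genes 3023 were higher and 2216 lower, with 7002 at an unadjusted p under 0.05. The median over all genes was itself shifted by 0.28. Without the first normal lung array the counts were 912 and 1342, and without the second 1104 and 1277.

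Fibroblast lines gave a comparison with normal cells in culture. MAL2, a membrane trafficking protein of polarised epithelia, was higher in SCLC lines by 5.83 (SE 1.31, adjusted p = 0.000795), and the epithelial adhesion molecule EPCAM by 5.29 (SE 1.45, adjusted p = 0.0079), each above both fibroblast lines in 63 of 64 lines. BEX1 (5.27), the junction receptor CXADR (4.75), TPD52 (4.72), CD24 (4.70), TSPAN7 (4.58), the epithelial splicing regulator ESRP1 (4.52), NCAM1 (4.45) and KIF5C (4.44) followed. GLIPR1 stood at -7.21 (SE 0.75, adjusted p = 5.31e-12), and the other genes with the lowest differences were CAV1 (-6.88), DCN (-6.56), TGFBI (-6.42), the collagen COL12A1 (-6.07), THBS1 (-6.00), the collagenase MMP1 (-5.96), CPED1 (-6.24), NT5E (-6.21) and the BMP antagonist GREM1 (-5.86). Of 23 mesenchymal genes 21 were lower (22 adjusted over the list alone, adjusted p = 1.88e-37, and adjusted p = 6.86e-05 with an estimated correlation), and of 17 YAP and TEAD targets 14 (15 adjusted over the list alone, adjusted p = 4.60e-20, and adjusted p = 0.00419 with an estimated correlation), with the matricellular CCN2 at -5.51 and the receptor kinase AXL at -4.36. The neuroendocrine list had 10 of 27 members higher (17 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), with SYT4 at 3.92 and SCG3 at 3.73. The cell cycle list had 9 of 40 (11 adjusted over the list alone, adjusted p = 0.498 with an estimated correlation) and the epithelial list 4 of 19 (4 adjusted over the list alone, adjusted p = 0.434 with an estimated correlation). The list of glutathione genes and NRF2 targets was lower on balance (2 of 19 members past the threshold, 4 adjusted over the list alone, adjusted p = 0.0408, and adjusted p = 0.531 with an estimated correlation). The pro-apoptotic BCL2L11 was higher by 2.44 and BCL2 by 2.06. Over all genes 644 were higher and 1098 lower, with 3494 at an unadjusted p under 0.05. Without MRC-9 the counts were 158 and 478, and without WI-38 137 and 518.

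Probe sets along a gene can differ in their ratio to the rest of the gene, which can mark exon usage. Such a ratio alone does not show it, since probe sets may also follow the level of their gene unequally. Which of these holds for the genes named here, INSM1 among them, was not tested. Among 6771 genes expressed in both SCLC and NSCLC lines, limma diffSplice called 304 (885 at an unadjusted p under 0.05), and 556 were called when each probe set kept its own spread, 191 by both. In C19orf33 1 probe set was lower in SCLC lines by 4.29 relative to the rest of its gene (a relative log2 difference of -4.29), with a Simes adjusted p of 2.13e-45. Probe sets of DYNC1I2, an intermediate chain of dynein (2.95), INSM1, a transcription factor of neuroendocrine cells (3.60), and TPD52L2 (2.86) were relatively higher, and one of the collagen COL6A2 was relatively lower (-2.83). All 5 genes were called by both tests, in C19orf33 on another probe set with the opposite sign (1.75 with its own spread). Of 8 genes of known alternative splicing that could be tested, ENAH, an actin regulator with an epithelial exon, was called by both, but on different probe sets with opposite signs (1.60, adjusted p = 0.028, by diffSplice and -0.86, adjusted p = 0.0236, with its own spread). The tropomyosin TPM1 was called by diffSplice only (-2.54, adjusted p = 1.23e-05, and adjusted p = 0.126 with its own spread). BIN1 was called with its own spread only (adjusted p = 0.000955), and PKM, NUMB, CLSTN1, CTNND1 and MEF2D by neither. Of its calls, 42.1% were left in number without NCI-H1650 and 55.9% without NCI-H2066. On simulated data it called 172 unchanged genes beside 175 of the 200 changed ones, against 13 and 172 with each probe set's own spread.

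Regulators that define subtypes of SCLC were examined across the 64 lines, with a gene counted as expressed where it lay above the median of all genes on that array. INSM1 was expressed in 64 of 64 lines by this cut, at 7.86 to 10.46. The cut sets a gene against other genes on the array and does not show detection above background. INSM1 also passed the like cut of the exon test in the mean of the NSCLC lines, so the count does not set SCLC lines apart. POU2F3, the regulator of tuft cells, lay at 11.79 in NCI-H526, 11.75 in NCI-H211 and 11.06 in NCI-H1048, and at 7.95 or below in the others. YAP1 was expressed in 11 lines, highest in NCI-H841 (9.99), NCI-H1341 (9.59), DMS114 (9.58) and NCI-H196 (9.53). MYCN reached 12.79 in NCI-H69, 12.67 in NCI-H249, 12.59 in NCI-H526 and 11.57 in NCI-H720, and 9.19 at most elsewhere. MYC fell into clusters of 42 and 22 lines, MYCL of 41 and 23, SLFN11 of 30 and 34 and YAP1 of 49 and 15, so their relations were computed within clusters. No wide gap parts these clusters. The lower YAP1 cluster ended at 6.78 and the higher began at 6.86. The like values were 8.56 and 8.69 for MYCL, 6.87 and 7.06 for SLFN11 and 8.04 and 8.63 for MYC. The lung lineage factor NKX2-1 was expressed in 49 lines, SLFN11 in 33, RB1 in 31 and REST in 16. None of 84 relations between these genes passed the threshold by Spearman rank correlation. For the 4 clustered genes these tests leave out any relation between the clusters, which was not tested. The smallest p was that of REST with INSM1 over 64 lines (rho = -0.381, permutation p = 0.00188, adjusted p = 0.158; r = -0.551, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 0.00084; r = -0.447 without the 2 lines with the most extreme REST).

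**Figure D2:**
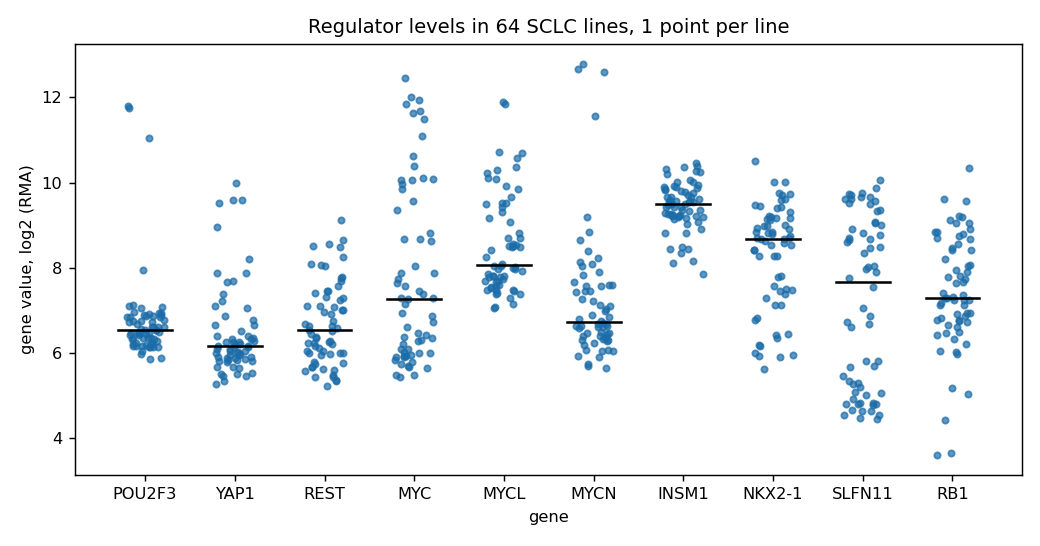
Gene values (log2, y axis) of 10 regulators (x axis) in the 64 SCLC lines, with 1 point per line and a bar at the median. POU2F3 stands above 11 in 3 lines and MYCN in 4, while SLFN11 spreads from 4.44 to 10.06.

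Drug response was set against expression over the SCLC lines. SLFN11, which blocks replication under DNA damage, was the gene most closely associated with the IC50 of the topoisomerase inhibitor topotecan. Its level fell by 1.17 on the log2 scale for each log10 unit of IC50 (95% interval -1.62 to -0.722, n = 63, limma adjusted p = 0.0349), so lines with more SLFN11 had a lower IC50. It was the only gene called for topotecan (1294 at an unadjusted p under 0.05), and 9 of 100 permutations of the IC50 values called 1 gene or more. Without NCI-H660 and NCI-H720, which cell repositories list under other diagnoses, the slope was -1.19 and no gene passed (adjusted p = 0.0587). For paclitaxel, which stabilises microtubules, GLYATL2, of the glycine acyltransferase family, was called alone (slope 0.43 per log10 unit, SE 0.08, adjusted p = 0.0201), and 7 of 100 permutations called 1 gene or more. With the overall drug sensitivity of a line as covariate the slope was 0.38 with a larger SE of 0.12, which did not pass (adjusted p = 1.00). No gene was called for etoposide (1195 at an unadjusted p under 0.05), doxorubicin (1254), vincristine (778) or gemcitabine (1073) by limma. SLFN11 had a slope of -1.32 for etoposide (adjusted p = 0.177; 0.0108 with overall sensitivity as covariate) and of -1.18 for doxorubicin (adjusted p = 0.312). All 63 lines lay at the top value for cisplatin, so it was not tested.

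Within the clusters of SLFN11, none of the 7 drugs tested passed for a relation to its level in the lower cluster, and 5 did in the higher cluster, among 14 tests. Levels in the lower cluster (4.44 to 6.73) lay below the median of all gene values (7.34), where a relation may be hard to see. The 5 are not separate results, since related drugs share their lines (rho = 0.987 for teniposide with etoposide over 59 SCLC lines). For topotecan the higher cluster had rho = -0.422 (n = 34, permutation p = 0.0134) and r = -0.296 (permutation p = 0.0881). Irinotecan had rho = -0.518 (n = 32, permutation p = 0.00281) and r = -0.510 (permutation p = 0.0029), and etoposide rho = -0.432 (n = 32, permutation p = 0.014) and r = -0.425 (permutation p = 0.0153). Teniposide had rho = -0.475 (n = 32, permutation p = 0.0068) and r = -0.436 (permutation p = 0.0124), and mitoxantrone rho = -0.433 (n = 34, permutation p = 0.0117) and r = -0.379 (permutation p = 0.0273). The adjusted p of each of these rho was 0.0392, while by r only irinotecan passed (adjusted p = 0.0406, and from 0.0714 to 0.247 for the others). With the mean over probe sets rho passed for irinotecan only (adjusted p = 0.0406). Without the 2 lines farthest from the median SLFN11 level, r was -0.348, -0.493, -0.420, -0.437 and -0.375. Whether the clusters differ in this relation was not tested. Given the overall drug sensitivity of the lines, the partial rank correlations were -0.314, -0.449, -0.336, -0.394 and -0.334, and none passed after adjustment (smallest adjusted p = 0.143). Among 22 other pairs of a gene and a drug fixed in advance none passed. The closest were the efflux pump ABCG2 with mitoxantrone (rho = 0.278, permutation p = 0.0278; r = 0.242, permutation p = 0.0506; adjusted p of rho 0.349; r = 0.321 without 2 lines) and the reductase NQO1 with the HSP90 inhibitor tanespimycin (rho = -0.272, permutation p = 0.0317; r = -0.354, permutation p = 0.00459; adjusted p of rho 0.349; r = -0.248 without 2 lines).

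**Figure D3:**
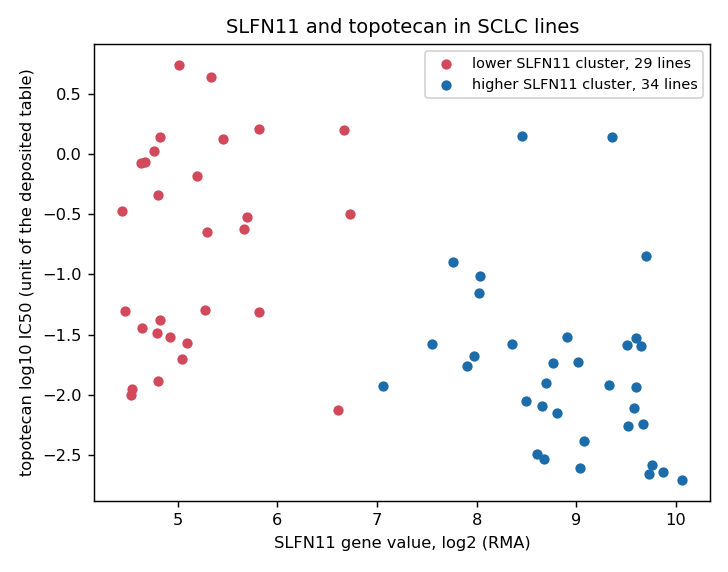
SLFN11 gene value (log2, x axis) against the log10 IC50 of topotecan (y axis) in 63 SCLC lines, 1 point per line, coloured by the cluster of SLFN11 level. The 34 lines of the higher cluster (7.06 to 10.06) lie mostly below an IC50 of -1, and the 29 of the lower cluster spread from -2.13 to 0.74.

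Gene lists moved with the IC50 of the 6 drugs in 34 of 132 tests with the preset correlation, and in 0 with an estimated one. Of 21 interferon response genes, 21 had a positive slope on vincristine IC50 and 9 passed adjusted over the list alone, none over all genes (adjusted p = 1.08e-13, and adjusted p = 0.329 with an estimated correlation). Of 27 neuroendocrine genes, 27 had a positive slope on paclitaxel IC50 and 24 on doxorubicin IC50, with 2 and 4 past adjusted over the list alone (adjusted p = 0.502 with an estimated correlation for both). With overall drug sensitivity as covariate the doxorubicin call was lost (adjusted p = 0.879). Of 19 epithelial genes, 18 had a negative slope on etoposide IC50, 9 of them past adjusted over the list alone (adjusted p = 0.502 with an estimated correlation).

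Pairs of structurally related compounds were compared line by line. Irinotecan, a prodrug of the camptothecin family, had a log10 IC50 higher than topotecan in 59 of 59 lines, by 1.73 (SD 0.487, 95% bootstrap interval 1.60 to 1.85). Of its values 20 lay at the top value, and without these lines the difference was 1.92. Teniposide, which carries a thienyl group in place of the methyl group of etoposide, was lower than etoposide in 59 of 59 lines, by a log10 difference of -0.946 (SD 0.188, interval -0.991 to -0.896). Gemcitabine, the difluoro analog of deoxycytidine, differed from cytarabine, with 31 values at the top, by -1.60 (-1.85 to -1.37), pralatrexate from methotrexate by -0.574 (-0.736 to -0.396; -0.880 without tied lines) and vincristine from vinblastine, in which a methyl group replaces the formyl group, by -0.245 (-0.339 to -0.141; -0.162 without tied lines). Each of these 5 had a sign-flip permutation p of 1e-05, the smallest the permutations can give (adjusted p = 1.8e-05). Clofarabine differed from cladribine by -0.186 (-0.275 to -0.0917, permutation p = 0.00015, adjusted p = 0.000225, median -0.117) and thioguanine from mercaptopurine by 0.0978 (0.0139 to 0.184, permutation p = 0.03, adjusted p = 0.0386, median 0.0327, and 0.169 without tied lines). For daunorubicin and doxorubicin, which differ by 1 hydroxyl group, the mean difference of -0.0772 (-0.160 to 0.0218, permutation p = 0.101) did not pass, although the median difference of -0.113 did (adjusted p = 0.00417). Docetaxel and paclitaxel differed by -0.0539 (-0.193 to 0.122, permutation p = 0.544), with 23 docetaxel values at the bottom of the range, and by a median of -0.200 (adjusted p = 4.5e-05). Across lines teniposide and etoposide correlated at r = 0.967 and rho = 0.987, and daunorubicin and doxorubicin at r = 0.844 and rho = 0.866 (permutation p = 1e-05 each, adjusted p = 1e-05, with r = 0.978 and 0.895 without 2 lines). The other pairs fell into clusters of IC50.

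**Figure D4:**
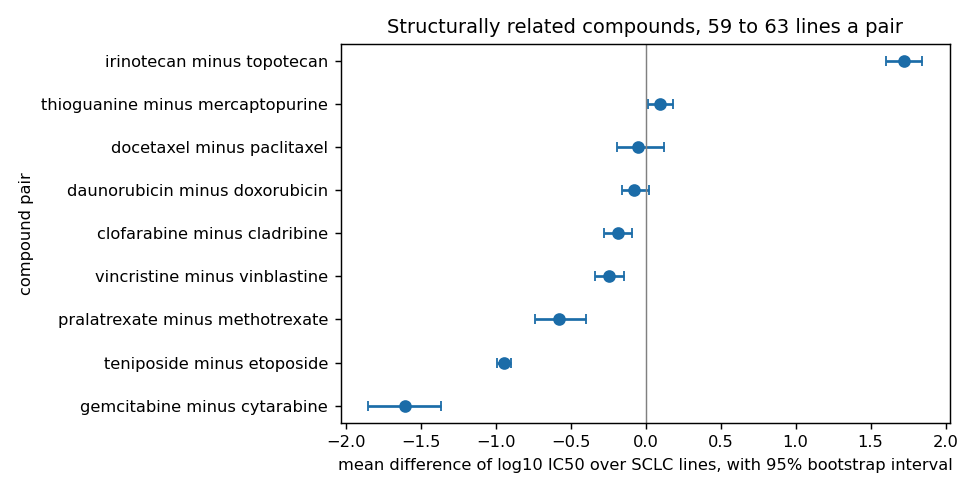
Mean paired difference of log10 IC50 (x axis) over 59 to 63 SCLC lines for 9 pairs of structurally related compounds (y axis), with 95% bootstrap intervals as bars. The intervals of docetaxel minus paclitaxel and of daunorubicin minus doxorubicin include 0, and the other 7 exclude it.

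The derivatives of NCI-H69, each selected differently and measured on 1 array, were set beside their parent with no test. ABCB1, the multidrug efflux pump, was higher by 7.36 in NCI-H69/LX10 and by 6.62 in NCI-H69VCR/R, at 12.07 and 11.33 against 8.80 at most in the 64 SCLC lines, and by 0.45 in NCI-H69/CPR. ABCB1 stood at 4.72 in NCI-H69, near the lowest SCLC value (4.33), so the exact size of these differences is uncertain. Its neighbour ABCB4, a phospholipid transporter, was higher by 3.65 and 3.77. The drug transporters ABCC1 (-0.30 and -0.84) and ABCG2 (-0.21 and 0.57) moved by under 1 in these lines. NCI-H69/CPR had its largest positive differences in PPP1R17 (4.85), the calcium-binding CALB2 (4.58), the RNA-binding IGF2BP1 (3.62), UBE2E2 (3.57) and LRRC8C (3.56). NRN1, a neuronal surface protein, was higher by 6.55 in NCI-H69/LX10, and WIPF1, an actin regulator, by 4.09 in NCI-H69VCR/R, where MAL2 (-5.70) was lower. Genes that differed by over 2 numbered 54 higher and 160 lower in NCI-H69/CPR, 89 and 168 in NCI-H69/LX10 and 117 and 154 in NCI-H69VCR/R. Of these, 75 differed the same way in all 3, of which 57 were lower, among them MSX2, a homeobox factor (mean -5.66), NELL2 (-5.64), LUZP2 (-4.87), the ubiquitin ligase MARCHF7 (-4.80), FAM241A (-4.64) and FGF14 (-4.28). ENPP2, which makes lysophosphatidic acid (-4.19), and SOCS2 (-3.82) belong to them too. The other 18 were higher, among them UBE2E2 (3.94) and IGF2BP1 (3.84). All 3 were compared with the same NCI-H69 array, which alone can give shared differences. The labels number the arrays of the derivatives 68, 69 and 70 and that of NCI-H69 7. Whether these numbers follow the order of processing is not stated. An effect of that order on shared genes or list medians cannot be told apart from a change in the derivatives. With the mean over probe sets the count was 46, of which 44 are among the 75. FAM241A then stood at -0.69, -1.11 and -0.74 in the 3 lines, and LUZP2 at -2.34, -2.52 and -2.51. Under it MSX2 stood at -3.40 in NCI-H69VCR/R, against -6.40 with the median.

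Glutathione genes and NRF2 targets had low medians in the 3 derivatives (-0.36, -0.60 and -0.65; percentiles 1.16, 0 and 0 among 10000 random lists matched on level), led by the reductase NQO1 (-2.63, -1.99 and -1.44). All list medians here set 1 array against the same parent array, and random lists lack the correlation of list members (0.558 for the epithelial list), so the percentiles are descriptive and not tests. The median of the epithelial list lay at 0.47 in NCI-H69/LX10 (percentile 99.9), with the cadherins CDH1 at 2.46 and CDH3 at 2.24, and at -0.63 in NCI-H69VCR/R (percentile 0.01), with ESRP1 at -2.62 and CLDN7 at -2.59. DNA damage response genes had a median of -0.60 in NCI-H69/CPR (percentile 0.04), with the kinases CHEK1 at -1.65, WEE1 at -1.41 and ATM at -1.32, and of -0.28 in each of the other 2 (percentiles 1.03 and 4.64). The Notch pathway list had a median of 0.51 in NCI-H69/CPR (percentile 99.97). On this array the alveolar and airway list (0.61, percentile 99.57) and the leukocyte list (0.59, percentile 98.41) were higher as well. Its probe set values had a narrower range, with quartiles of 5.94 and 8.75 against 5.82 and 8.83 in NCI-H69. An effect of that range on its list medians cannot be told apart from a change in these genes. In drug response, log10 IC50 was higher than in NCI-H69 by over 1 for 85 of 222 compounds in NCI-H69/LX10, 104 in NCI-H69VCR/R and 4 in NCI-H69/CPR, and lower by over 1 for 0, 1 and 7. Paclitaxel went from -2.52 in NCI-H69 to 0.48 and 0.91 in the first 2 and vincristine from -2.60 to 0.36 and 0.78, while paclitaxel had -2.51 in NCI-H69/CPR. Doxorubicin went from -1.18 to 0.83 and 1.00. Oxaliplatin, a platinum agent, stood at -0.03 in NCI-H69 and at the top value of 1.00 in NCI-H69/CPR and NCI-H69VCR/R; cisplatin and carboplatin were at the top value in all 4 lines.

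**Figure D5:**
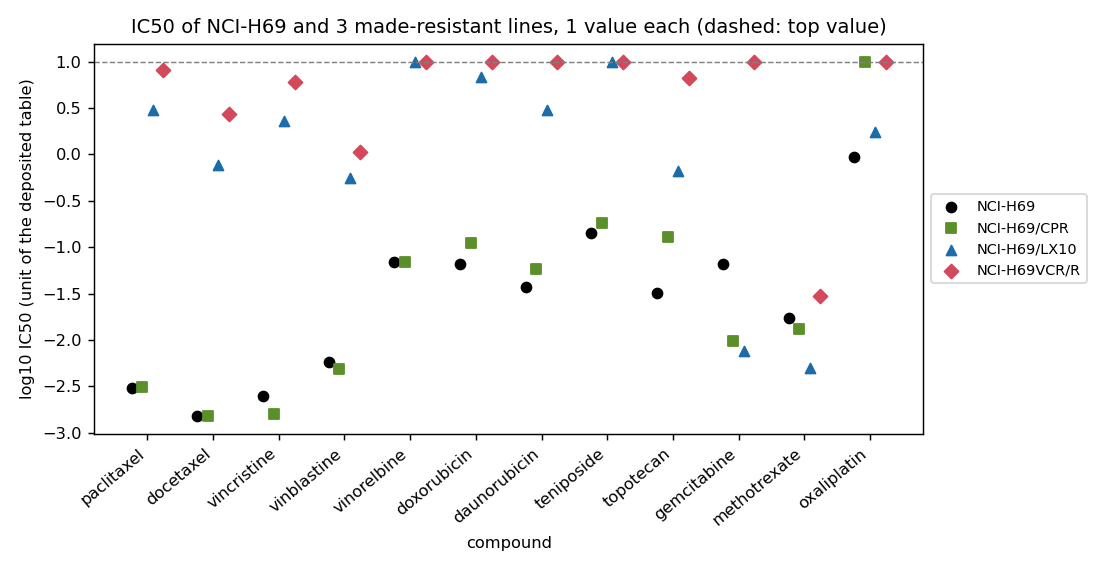
Log10 IC50 (y axis, unit of the deposited table) of 12 compounds (x axis) in NCI-H69 and 3 made-resistant lines, 1 value per line, with the top value dashed. NCI-H69/LX10 and NCI-H69VCR/R lie far above NCI-H69 for paclitaxel (0.48 and 0.91 against -2.52), and NCI-H69/CPR lies apart from it for oxaliplatin (1.00 against -0.03).

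The single arrays of normal adrenal RNA and of the mesothelioma line were set beside the range of the SCLC lines, without a test. In adrenal RNA all 12 adrenal cortex genes lay above every SCLC line, with the steroid enzymes HSD3B2 at 13.29, CYP17A1 at 13.27 and CYP11A1 at 12.78 and the cholesterol carrier STAR at 13.22, each against 6.61 at most. The catecholamine enzymes TH (11.30) and PNMT (10.90) also lay above the range, with 4 of 8 adrenal medulla genes, while 35 of 40 cell cycle genes lay below it. In the mesothelioma line the co-activator WWTR1 (11.34), CRIM1 (11.04) and the phosphatase PTPN14 (11.24) lay above every SCLC line, as did the transporters ABCC2 (11.14), ABCC3 (11.13) and ABCC4 (11.22), and the exocytosis protein SNAP25 (5.36) lay below. Of all genes, 904 lay above and 1090 below the SCLC range in adrenal RNA. In the mesothelioma line 4.6% of genes lay above it and 3.1% below.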

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

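All compounds known by number only were scanned after the first drug results were seen, and the test of neighbours of FADD was chosen after the genes were seen; the other 2 tests given here were chosen before their values were seen. Of 194 such compounds, 97 had 1 or more genes past the threshold of the limma regression over SCLC lines. They stand here as a signal in data that the comparisons above do not use. Over all 222 compounds 108 had a call, against a median of 16.5 and at most 38 in 10 permutations of the lines.

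With 1 of these compounds 90 genes passed, which is a second signal of that kind. ADAM3A, a pseudogene of a metalloproteinase, KERA, a cornea proteoglycan, KDM6B, a histone demethylase, and FADD, an adaptor of death receptors, had the smallest p-values. The log10 IC50 of the line DMS114 was -1.37, against 0.271 in the next line and a median of 0.798, and ADAM3A lay at 8.97 in it, against 4.47 at most in other SCLC lines. A single line may account for these calls, since 0 genes were left without DMS114. A stretch of neighbouring genes raised in that line fits for 4 of the 90, which lie within 30 measured genes of FGFR1 (ADAM32, ADAM3A, IDO1 and THAP1), 11.5 times the share of all genes, in a stretch with a median difference of 0.77 from the other lines (FGFR1 itself did not pass, adjusted p = 0.627). Another 13 lie within 30 of FADD, 37.4 times that share, but that window was centred on a called gene. Of its 61 genes 17 are highest in DMS114, as around FGFR1 (567 of 15778 overall), with a median difference of 0.03, so a raised stretch there cannot be told apart from single raised genes, and no biological explanation was tested.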

How the results depend on the processing

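Alternatives were chosen before the data were examined, except the exon test with its own spread per probe set, the fits without DMS114, the clusters of IC50, the counts without marker lists, the scan of all compounds and the adjustment of lists within a comparison, which were chosen after seeing the data. Of 129 values of named genes in the group comparisons, 101 kept their direction and side of the threshold under every alternative, and none reversed. Most of the other changes came from leaving out 1 array of a small group, after which the array left was assumed to vary like the other groups. No paired analysis was possible because the replicate numbers only follow the order of the samples. The number of arrays limits the precision. Where no cause is given below, the cause was not tested.

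Leaving out 1 NSCLC line gave 435 to 513 genes higher and 681 to 840 lower. Leaving out 1 normal lung array gave 912 to 1104 higher and 1277 to 1342 lower, and leaving out 1 fibroblast line 137 to 158 higher and 478 to 518 lower. With a log2 difference of 1 or more also required, which keeps fewer genes by construction, 771 genes were lower than in NSCLC lines and 1612 higher than in normal lung RNA. Other settings kept each count of genes within 1.5 times. Exon usage calls ranged from 1.3e+02 (42.1% of the 304) to 296 genes without 1 NSCLC line, and numbered 556 with each probe set's own spread. With the correlation estimated per list, 11 of 25 list calls between groups and 0 of 34 list calls with drugs were left. With fry 3 list calls between groups were lost, mesenchymal against NSCLC lines (adjusted p = 0.0806), and cell cycle (adjusted p = 0.0543) and glutathione and NRF2 targets (adjusted p = 0.0534) against fibroblast lines.

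For etoposide 4 genes passed with overall drug sensitivity as covariate, for topotecan 0 without NCI-H660 and NCI-H720, and for paclitaxel 2 with the mean over probe sets and 7 with ranks of IC50. With overall sensitivity as covariate the direction turned for the neuroendocrine list with etoposide (adjusted p = 0.568) and topotecan (adjusted p = 0.460), the interferon response list with topotecan (adjusted p = 0.608) and doxorubicin (adjusted p = 0.0805), the tuft cell list with vincristine (adjusted p = 0.537) and the class I antigen presentation list with paclitaxel (adjusted p = 0.316). Another 8 of the 34 list calls with drugs were lost with this covariate, with adjusted p from 0.0644 to 0.963, and 20 kept. Calls were also gained, since 44 of all 132 tests passed with it. By Pearson correlation 4 relations between regulators passed. Of the pooled pairs of a gene and a drug 1 passed by partial rank correlation given overall sensitivity, NQO1 with tanespimycin (-0.403, adjusted p = 0.0257). Within clusters 1 pair passed by Pearson correlation, 1 with the mean over probe sets and 0 by partial rank correlation. The difference of daunorubicin and doxorubicin was -0.113 as a median, and that of docetaxel and paclitaxel -0.200 as a median and 0.106 without lines at the most common value. With the mean over probe sets 116, 159 and 171 genes differed by over 2 in NCI-H69/CPR, NCI-H69/LX10 and NCI-H69VCR/R, and 46 the same way in all 3. ABCB1 then stood at 6.50 and UBE2E2 at 3.12 in NCI-H69/LX10, and ABCB4 at 3.07 in it and 2.98 in NCI-H69VCR/R. With quantile normalization ABCB4 stood at 0.13 in NCI-H69/CPR.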

Other observations

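SLFN11 was also called for compounds other than topoisomerase inhibitors in a scan of all compounds. The p-values of this scan were adjusted over genes for each compound and not over compounds. How often SLFN11 is called with permuted lines was not counted. Over all 222 compounds, scanned after the first drug results were seen, SLFN11 was the gene with the smallest p and past the threshold in 7, each with lower SLFN11 at a higher IC50. Among them were the DNA alkylating agents thiotepa (slope -2.8 on the log2 scale per log10 unit, limma adjusted p = 0.0015, n = 63), mitomycin (-1.39, adjusted p = 0.00311, n = 63) and triethylenemelamine (-1.74, adjusted p = 0.00442, n = 63), beside irinotecan (-1.92, adjusted p = 0.00269, n = 59) and topotecan. ABCB1 passed for 3 compounds. The interferon-induced IFIT1 was the top gene for the histone deacetylase inhibitor vorinostat (slope 1.4, adjusted p = 0.00942, n = 63), with 44 genes past the threshold, and BCOR, a transcriptional corepressor, for tanespimycin (slope 0.38, adjusted p = 0.0238, n = 63). These genes and drugs were chosen after their values were seen.

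For SLFN11 and topotecan the test with overall drug sensitivity was chosen after the result was seen, and the others before. The slope of SLFN11 was -1.93 with overall drug sensitivity of the lines as covariate and -1.19 with the mean of the neuroendocrine list as covariate. Without the 6 lines with the most extreme IC50 it was -1.11 (95% interval -1.67 to -0.551), although SLFN11 then missed the threshold over all genes (adjusted p = 0.341). None of these tests accounts for the association over the 63 lines. The sensitivity covariate averages 222 compounds, topotecan among them. Given it, the partial rank correlation within the higher SLFN11 cluster was -0.314 and did not pass (permutation adjusted p = 0.197). For topotecan 9 of 100 permutations of the IC50 values called 1 gene or more.

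For the 75 genes that differ the same way in the 3 derivatives of NCI-H69, the test of their origin was chosen after the result was seen and the others before. NCI-H249 lay nearer to the derivatives than to NCI-H69 at 53 of the 75, but these genes were chosen because NCI-H69 differs there, so an NCI-H69 array that stands apart cannot be told apart from a shared change by this test. Against NCI-H249 in place of NCI-H69 the count was 61, with 12 genes in common. In 100 simulations of unchanged arrays the highest count was 42, which is below 75 but not by the margin set in advance. The simulations used the spread among the 3 derivatives, which also holds differences between these lines. ABCB1, for example, stood at 5.17 in NCI-H69/CPR, 12.07 in NCI-H69/LX10 and 11.33 in NCI-H69VCR/R. That spread is therefore not array noise alone, and noise of the NCI-H69 array cannot be told apart by this test. No biological explanation was tested. NCI-H69 ranked 2 or better among SCLC lines by correlation with each derivative, but NCI-H249 correlated better with NCI-H69/LX10 (0.9329 against 0.9285 across genes). The rank therefore does not exclude another origin near NCI-H249, and derivatives that are not from NCI-H69 cannot be told apart by it.

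Random splits of the NSCLC and SCLC lines into groups of 3 and 64 were drawn 100 times with the real one among them, a test chosen before its result was seen. For genes 1 split, the real one, reached 2047 calls, and the highest other had 276, so chance can be excluded at this number of splits. For lists adjusted within this comparison, 7 splits reached the real 8, and the highest other had 10, so chance cannot be excluded. With the correlation estimated per list 8 splits reached the real 1, and the highest other had 2, so chance cannot be excluded. For exon usage 5 splits reached the real 304, and the highest other had 794, so chance cannot be excluded. With each probe set's own spread 4 splits reached the real 556, and the highest other had 1593, which is under the bound of 5 splits set in advance.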
